A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

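Liver RNA of rainbow trout (Oncorhynchus mykiss, 150 days old) was sequenced in 6 libraries, 3 from fish kept at 18 °C and 3 from fish whose water was warmed by 1 °C each 24 h until it reached 24 °C, per the labels' protocols. The libraries were made from RNA depleted of ribosomal RNA, with random primers and with dUTP in the second strand, per the labels' protocols. The extraction text of those protocols names retinas, whereas the tissue label of every sample is liver, which was used here. Fish were divided into tanks by group, and which tank each library came from is not given in the sources used here. Bowtie2 2.2.8 and TopHat2 2.1.1 were used by the authors, per the submitters' processing notes. The quantifier, the genome build and whether counting used strand are not given in the sources used here.

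Each library had 1 table of lncRNA transcripts, with an estimated count of reads and an FPKM value per transcript. The estimated counts were made by the authors without normalization and were deposited as such, per the file headers and values. Between 10.5% and 13.1% of the values of a library had a fractional part, as estimated counts can have where a read is divided between similar transcripts. These shares include values at 0. Among the values above 0 of a library, 31.9% to 37.9% were fractional. The FPKM values were scaled by the authors per kilobase of transcript and per M fragments of the library (M stands for 1000000), per the file headers and the ratio of count to FPKM. The complete list has 5916 transcripts, 4989 known ones with RefSeq identifiers followed by 927 assembled ones (TCONS identifiers), made with Cufflinks per the source column of their exon table. The tables held here for control replicate 1, heat replicate 1 and heat replicate 3 end inside a line, after 2186, 1498 and 3413 transcripts of the list. The incomplete last line was dropped, and the rest of the list was treated as not measured here, never as 0. All 6 tables follow the same order, so the first 1498 transcripts, all of them known, had a value in every library. The exon table of assembled transcripts also ends inside a line and covered 225 of them, of which 224 were complete.

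Because part of a list does not give a library's depth, the depth was recovered from the values. A count divided by its FPKM and by the transcript length gives the total used by the authors. In control replicate 2, 5 assembled transcripts with known exons and at least 300 reads gave totals of 29.96 to 29.99 M fragments. The ratio of count to FPKM over 15 known transcripts with at least 100 reads in every library then gave the other totals. Exon lengths gave the same 28.58 M for control replicate 3 and 28.30 M for heat replicate 2. The lengths of known transcripts quoted below come from the same relation.

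Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM factors, robust quasi-likelihood fits and two-sided quasi-likelihood F tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Fold changes are heat over control. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over that group, which covers counting error only, not the scaling or how reads were assigned. These bounds use TMM-scaled library sizes. With the implied library totals the bounds of rises would be smaller and those of falls larger. The main test used all 6 libraries and the transcripts held in all of them, with no covariate. Further fits were added after the incomplete tables were seen. They used 5 libraries (without heat replicate 1), 4 libraries (replicates 2 and 3 of each group) and the 3 libraries with complete tables (control replicates 2 and 3 and heat replicate 2). In the last, the lone heat library is assumed to vary as the controls do. The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes, with 40 changed transcripts in each of 10 simulations, a number set by the 226 transcripts tested. For the 6-library comparison (226 transcripts) it recovered 35.0% of 4-fold and 76.0% of 16-fold changes, and 4.72% of its calls were false. For the 5-library comparison (340 transcripts) the values were 25.0%, 69.5% and 8.25%, for the 4-library comparison (462 transcripts) 8.5%, 59.0% and 13.5%, and for the 3-library comparison (1511 transcripts) 3.0%, 31.5% and 19.8%.

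Levels are given as the authors' FPKM, mean ± SD. The labels' protocols name 12 female fish and say that total RNA was mixed, but not which fish make up each library, so a library may be a pool. SDs and p-values therefore measure the spread between these libraries, which may be technical. The named transcripts were chosen by a rule fixed at the same time as the gene lists below: among calls whose 3 heat values all lay on one side of the 3 control values and whose abundance was above the median of the tested transcripts, up to 10 in each direction, then the 5 most abundant calls in each direction, then calls next to a gene of a fixed list. This named 15 of the 18 calls, and the other 3 were added after their values were seen. Transcripts named from the added fits were also chosen after their values were seen. In all, 13 lists of protein-coding genes were fixed before the data were examined (heat shock and chaperones, endoplasmic reticulum stress, antioxidant defence, lipid and sterol metabolism, carbohydrate metabolism, immune and acute phase, apoptosis and cell cycle, proteasome, RNA splicing, hepatocyte secreted proteins, and markers of blood, exocrine pancreas and bile duct, stellate or endothelial cells). They were matched to the nearest protein-coding gene of each lncRNA in a RefSeq gene table of the assembly USDA_OmykA_1.1, used only for names and for which genes neighbour each other. Of 4989 known identifiers, 1373 (27.5%) matched that table once the version was dropped, and 5 with it. Alternatives were other scalings, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 0.01, other filters and thresholds, a replicate block, each library left out in turn, and the library totals in place of TMM.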

Results

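Long non-coding RNAs (lncRNAs) were measured by RNA sequencing in liver tissue of rainbow trout, a cold-water salmonid, kept at 18 °C or warmed to 24 °C. There were 3 control and 3 heat-stress libraries, and the stated purpose was to find lncRNAs induced by heat. The library totals implied by the authors' values were 27.9, 29.97 and 28.6 M fragments (M stands for 1000000) in control replicates 1 to 3. They were 41.2, 28.3 and 39.0 M in heat replicates 1 to 3. Over the 1498 known lncRNAs with a value in every library, the libraries held 76806, 73523 and 72058 estimated reads in the controls and 124458, 81419 and 100855 in the heat group. One transcript, XR_002468514.1 (LOC110489055), took 67.3% to 73.4% of those reads, so the other transcripts rested on far fewer reads. Counting error alone sets a floor: 0 reads allow up to 0.0728 reads per M fragments in heat replicate 1 and up to 0.108 in control replicate 1.

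**Figure D1:**
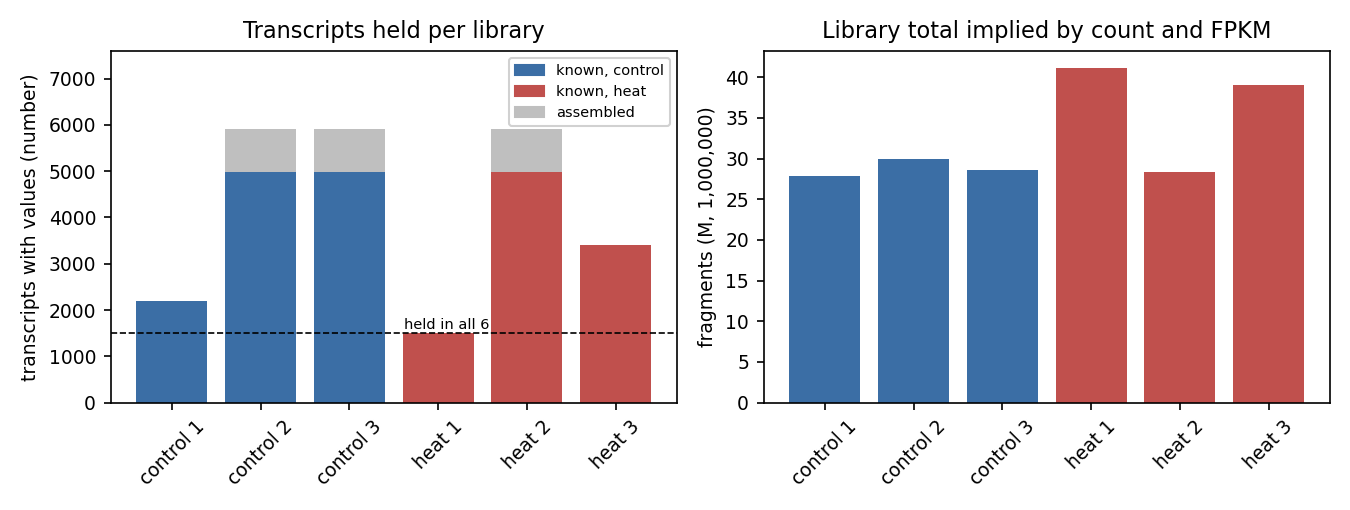
Left, number of lncRNA transcripts with a value in each library, known (coloured by group) and assembled (grey), with a dashed line at the 1498 held in all 6. Right, library total in M fragments implied by count, FPKM and length. All 5916 transcripts are present in 3 libraries, and heat replicates 1 and 3 are the deepest, at 41.2 and 39.0 M.

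Most known lncRNAs were silent or near the floor in these libraries. Among the 1498, a control library had reads in 490.0 ± 6.0 transcripts (SD, n = 3) and a heat library in 472 ± 22 (SD, n = 3). The difference between heat and control of -18.3 transcripts was not larger than the spread (two-sided exact permutation test, p = 0.3, where 0.1 is the smallest value that 3 against 3 allows). It was -7.00 without heat replicate 1 and -29.0 without heat replicate 3. The most abundant transcripts did not pass the test. XR_002468514.1 stood at 508 ± 51.2 FPKM in controls and 569 ± 58.8 FPKM in heat (SD, n = 3; log2 fold change 0.38 ± 0.15 SE, edgeR adjusted p = 0.22). XR_002469251.1 (LOC110494310) stood at 229.6 ± 69.7 and 212 ± 21.2 FPKM (log2 fold change 0.11 ± 0.29 SE, edgeR adjusted p = 0.87). Here the mean FPKM is lower in heat and the fitted fold is above 0, because FPKM uses the authors' totals and the fit uses TMM factors, so no direction is given.

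Libraries of the same group correlated more highly with each other than libraries of different groups. Spearman's rho of log2(reads per M fragments + 1), over 788 lncRNAs with a read in some library, was 0.628 to 0.678 for the 6 pairs within a group and 0.522 to 0.616 for the 9 pairs between groups. Pearson's r was 0.900 to 0.930 within groups and 0.768 to 0.827 between them. These are correlations across transcripts, which are not independent replicates. The mean rho was 0.0722 higher within groups, and the real grouping gave the highest value of the possible splits (one-sided exact permutation test, p = 0.1, the smallest the design allows).

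The comparison of heat with control asked which lncRNAs are induced by heat. Among calls with no control read, XR_002467886.1 and its neighbour in number XR_002467887.1 had the largest lower bounds. Under TMM scaling they were at least 1135-fold and 186-fold higher in heat (722-fold and 118-fold without control replicate 2). Among calls with reads in both groups, the largest rise was in XR_002467889.1 (log2 fold change 8.56, and 10.31 without control replicate 1) and the largest fall in XR_002469307.1, from 2.16 ± 0.365 to 0.0833 ± 0.0306 FPKM (SD, n = 3). Of 226 known lncRNAs with enough reads to test, 18 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 12 higher and 6 lower in heat, and 45 had an unadjusted p under 0.05. The called changes were large: the smallest was 1.77 on the log2 scale. The test recovered only 35.0% of simulated 4-fold changes, so the size of the calls partly reflects what it could detect. All 18 had heat values entirely above or entirely below the control values, as did 76 of the 226 tested (33.6%), where chance gives 10%. The transcripts share the same 6 libraries and are not independent, so the distance from 10% is not a test. The median log2 fold change was 0.02. Scaling by the library totals moved it to -0.17, a shift of 0.20, and gave 10 higher and 8 lower, with 16 of the 18 calls kept.

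A run of neighbouring identifiers rose. XR_002467886.1, 2069 bases long, had no read in any control library and reached 16.4 ± 3.36 FPKM in heat (SD, n = 3), at least 1135-fold higher (edgeR adjusted p = 0.0019). XR_002467887.1 also had no control read and reached 2.57 ± 0.955 FPKM (SD, n = 3), at least 186-fold higher (edgeR adjusted p = 0.0044). XR_002467889.1 went from 0.0933 ± 0.114 to 29.9 ± 12.9 FPKM (SD, n = 3), a log2 fold change of 8.56 ± 1.17 SE (edgeR adjusted p = 0.0072). Its fold rests on few control reads (11.79, 3.25 and 0 in replicates 1 to 3): the log2 fold change was 10.31 without control replicate 1 and 7.99 without control replicate 3. In heat it was the most abundant transcript of those that rose. The remaining member of the run, XR_002467888.1, missed the threshold (log2 fold change 5.77 ± 1.46 SE, edgeR adjusted p = 0.072), with 0.4, 8.27 and 2.71 FPKM in heat replicates 1 to 3, and passed it without heat replicate 1 (log2 fold change 6.39 ± 1.09 SE, edgeR adjusted p = 0.028). That value moved to 7.45 when control replicate 2 was left out too, to 5.65 when control replicate 3 was and to 5.33 when heat replicate 2 was. It stayed past the threshold only in the case of control replicate 2. Several of their counts are fractional, and whether reads were divided among them or with other transcripts is not known. The bounds above hold under TMM scaling and cover counting error only, and without control replicate 2 they were 722-fold and 118-fold. Scaling by the library totals would make them smaller. XR_002467889.1 and XR_002467888.1 held 15.04 and 15.37 control reads in all, so the folds of XR_002467886.1 and XR_002467887.1 would be smaller if some of these reads were theirs. No gene name was found for these identifiers in the reference table used here.

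A pair of lncRNAs with consecutive identifiers also rose. XR_002468948.1 (LOC110492088) rose from 0.663 ± 0.248 to 11.0 ± 1.96 FPKM (SD, n = 3; log2 fold change 4.28 ± 0.45 SE, edgeR adjusted p = 0.0029). Its nearest protein-coding gene is cd34a, 19444 bases away, related to the CD34 antigen of blood progenitor and endothelial cells. XR_002468947.1 (LOC110492087) rose from 0.437 ± 0.211 to 5.63 ± 3.99 FPKM (log2 fold change 3.94 ± 0.64 SE, edgeR adjusted p = 0.014). Heat replicate 2 stood at 10.23 FPKM and the other heat libraries at 3.31 and 3.34, and without it the log2 fold change was 3.18. The threshold was missed without control replicate 1, 2 or 3 (edgeR adjusted p = 0.113, 0.052 and 0.101). Its gene span overlaps that of the protein-coding gene LOC100136105 in the reference table. Strand and exons were not compared, so whether reads of LOC100136105 were counted for XR_002468947.1 is not known.

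Among the other transcripts that rose, XR_002469455.1 (LOC110495604) went from 2.30 ± 0.534 to 6.59 ± 1.39 FPKM (SD, n = 3). XR_002469317.1, only 189 bases long, went from 1.75 ± 0.357 to 9.49 ± 1.07 FPKM. XR_002468323.1 went from 0.930 ± 0.428 to 5.51 ± 1.84 FPKM, and XR_002469771.1 from 1.07 ± 0.887 to 5.78 ± 1.52 FPKM. XR_002469499.1 went from 0.347 ± 0.146 to 2.74 ± 0.311 FPKM. Their log2 fold changes lay between 1.77 and 3.18, with edgeR adjusted p between 0.0053 and 0.044. The remaining 2, XR_002469244.1 and XR_002469833.1, were among the 3 named after their values were seen. XR_002469244.1 (LOC110494287) had no control read and 0.510 ± 0.239 FPKM in heat, at least 22.7-fold higher under TMM scaling (less with the library totals). XR_002469833.1 went from 0.880 ± 0.0819 to 2.54 ± 0.646 FPKM. Leaving out control replicate 2 moved the log2 fold change of XR_002469771.1 from 2.70 to 3.56 and the limit of XR_002469244.1 to 14.4-fold. XR_002469317.1 and XR_002468323.1 were no longer called without control replicate 1 or 3, and XR_002469771.1 without either of these or heat replicate 2 or 3. XR_002469455.1 and XR_002469833.1 were called only where heat replicate 1 was the library left out, and XR_002469244.1 was not called without any 1 of the 6 (not tested without heat replicate 1 or 2). With all 6 libraries, XR_002469771.1 was also lost with size factors, upper-quartile scaling and library totals (edgeR adjusted p = 0.051, 0.061 and 0.065). XR_002469833.1 was lost in the same cases (edgeR adjusted p = 0.060 with library totals) and also with no filter on low counts.

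Of the 6 lncRNAs that fell, XR_002469307.1, 2946 bases long, had the largest fold among those with reads in both groups (log2 fold change -4.51 ± 0.42 SE, edgeR adjusted p = 0.0019). XR_002469142.1, 3338 bases long, went from 0.877 ± 0.140 to 0.0667 ± 0.0379 FPKM (log2 fold change -3.49 ± 0.45 SE, edgeR adjusted p = 0.0053). XR_002468831.1 stood at 0.550 ± 0.180 FPKM in controls and had no read in any heat library, at least 31.2-fold lower. XR_002468439.1 (LOC110488560), the other transcript named after its values were seen, stood at 0.747 ± 0.280 FPKM and was likewise at 0 reads in heat, at least 25.9-fold lower. XR_002468665.1 (LOC110490142) went from 1.41 ± 0.365 to 0.310 ± 0.125 FPKM (log2 fold change -1.94 ± 0.37 SE, edgeR adjusted p = 0.025). XR_002469203.1 (LOC110493863) went from 0.813 ± 0.160 to 0.197 ± 0.0586 FPKM (log2 fold change -1.83 ± 0.39 SE, edgeR adjusted p = 0.038). Without heat replicate 1 the limits of XR_002468831.1 and XR_002468439.1 were 17.6-fold and 14.6-fold, and without heat replicate 3 they were 20.6-fold and 17.2-fold. These and XR_002468665.1 were called only where heat replicate 1 was the library left out, and XR_002469203.1 was lost whichever library was left out. Each of the 6 had fractional counts in controls, and whether reads were divided with other transcripts is not known. Their tested neighbours in number were not called. The log2 fold changes of these were 0.93 (XR_002469306.1), 0.79 (XR_002469308.1), 1.17 (XR_002468830.1), -1.42 (XR_002468832.1), -1.38 (XR_002469143.1) and -0.07 (XR_002468440.1).

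**Figure D2:**
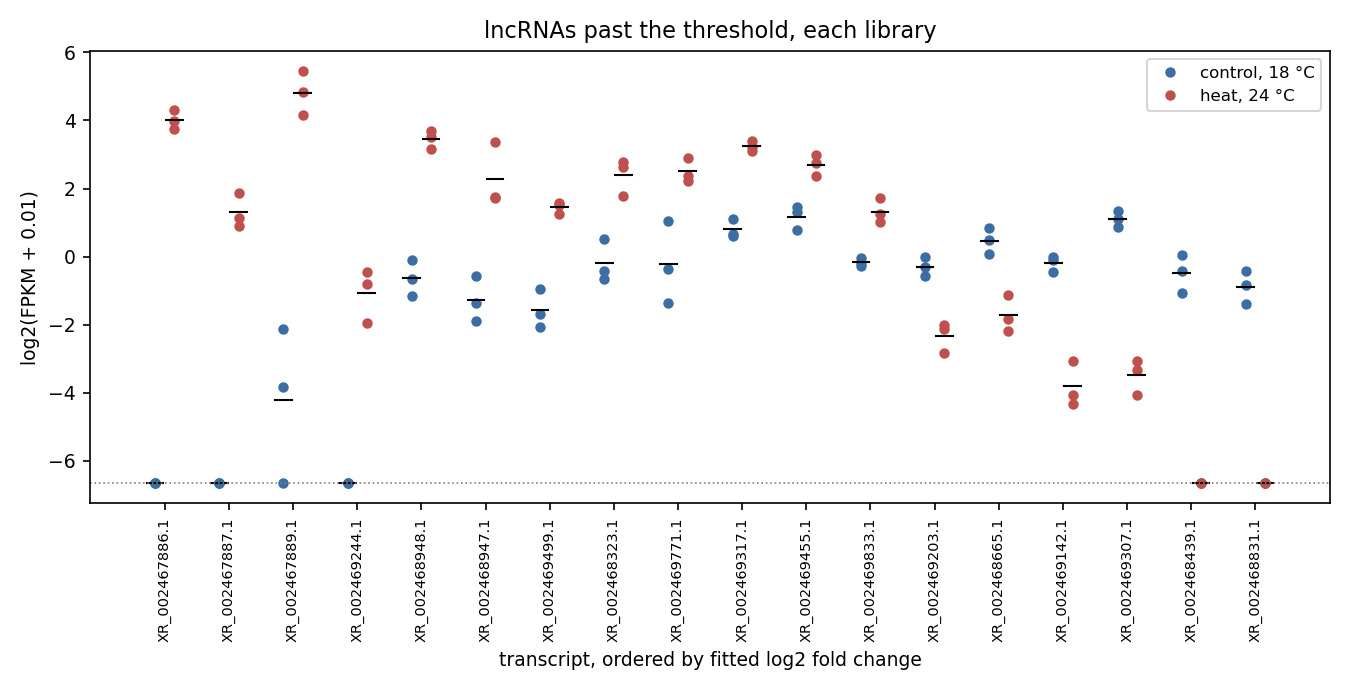
Level of each of the 18 called lncRNAs in each library, as log2(FPKM + 0.01), for the control (blue) and heat (red) libraries, with black bars at the mean of the 3 values and a dotted line at 0 FPKM. Heat and control values do not overlap for any of the 18.

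All 18 kept their direction in every alternative that tested them. Only 3 were called in all of the alternatives (XR_002467886.1, XR_002467887.1 and XR_002468948.1), and 7 stayed past the threshold whichever library was left out. These 7 were the same 3 with XR_002467889.1, XR_002469499.1, XR_002469307.1 and XR_002469142.1. XR_002467889.1 missed the threshold with no filter on low counts (edgeR adjusted p = 0.099), and XR_002469142.1 missed it with limma at a pseudocount of 0.01 (adjusted p = 0.064). All 4 missed it in the 3-library fit, and XR_002467889.1 also in the 4-library fit (edgeR adjusted p between 0.0507 and 0.0623). The number of calls fell to 7 without control replicate 1, to 7 without control replicate 3, to 10 without heat replicate 2 and to 11 without heat replicate 3. Of the other 11, 2 were called in 0 of the 6 fits with a library left out (XR_002469244.1 and XR_002469203.1) and 5 in only 1 of them.

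**Figure D3:**
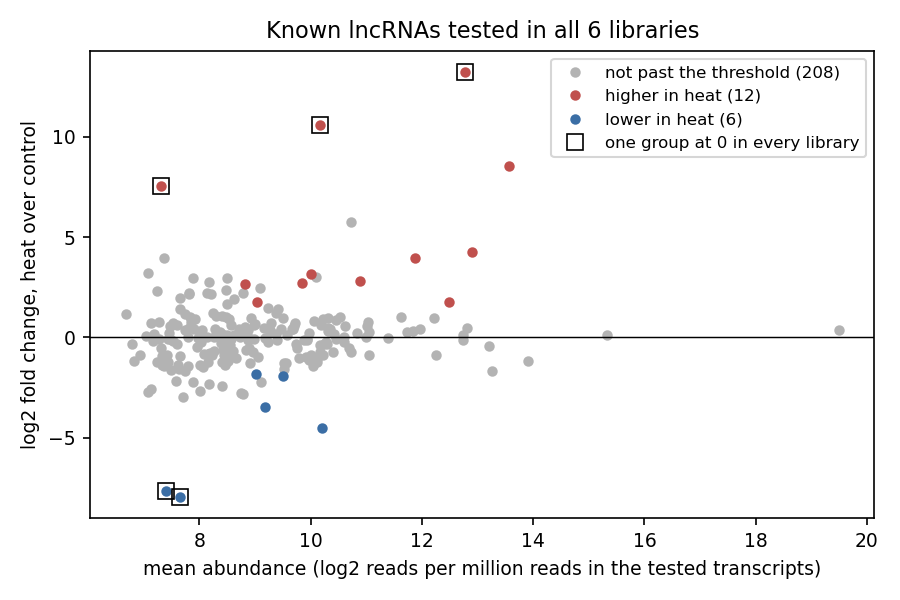
Fitted log2 fold change (heat over control) against mean abundance for the 226 tested lncRNAs, with the 12 higher (red) and 6 lower (blue) calls. Open squares mark the 5 calls with one group at 0 reads, whose fitted fold change depends on the added prior count and is no bound.

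The fixed gene lists could be used only for part of the data. Only 80 of the 226 tested lncRNAs (35.4%) could be placed beside a gene in the reference table. Of its protein-coding genes, 76% carry a symbol that starts with LOC. The lists were matched by symbol or synonym, so a list gene under such a symbol could be missed. Of the 13 lists, 12 had no tested lncRNA matched to one of their genes, heat shock and chaperone genes included. The lipid and sterol list had 1, the lowered XR_002468665.1, whose nearest protein-coding gene in the reference table is pparaa, 20.1 kb away, a PPAR alpha gene that regulates fatty acid oxidation. This call was lost in 5 of the 6 fits with a library left out, all but the one without heat replicate 1 (edgeR adjusted p from 0.063 to 0.101), and with a replicate block (edgeR adjusted p = 0.164). With 1 member no test of enrichment was made.

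More of the list could be compared where fewer libraries were used. Without heat replicate 1, the first 2186 transcripts had values in 3 control and 2 heat libraries, and 30 of 340 tested lncRNAs changed, 20 higher and 10 lower in heat. They included 16 of the 18 calls above, from mostly the same libraries, and 8 transcripts beyond the shared part of the list, 7 of them higher. The other 6 were not called with heat replicate 1 included: XR_002467888.1, XR_002469133.1, XR_002468829.1, XR_002468057.1 and XR_002468082.1 missed the threshold there, and XR_002468053.1 did not pass the filter. XR_002468057.1, for example, stood at 1.86 FPKM in heat replicate 1 and 1.93 to 2.28 FPKM in controls. The 8 have no value in heat replicate 1, so they lack this check. XR_002469880.1 (LOC110498850) had no control read and 2.53 and 1.49 FPKM in the 2 heat libraries, at least 157-fold higher (edgeR adjusted p = 0.012). XR_002469882.1 likewise had no control read and was at least 56.5-fold higher (edgeR adjusted p = 0.032). Both limits hold under TMM scaling, and the library totals would make them smaller. XR_002470119.1 (LOC110500534) rose from 0.887 ± 0.363 FPKM (SD, n = 3) to 7.20 ± 3.46 (SD, n = 2), and XR_002470209.1 from 0.717 ± 0.196 to 4.06 ± 0.255. The gene of XR_002470119.1 lies 136 bases from the protein-coding gene LOC110500532 in the reference table. XR_002470284.1, XR_002470147.1 and XR_002470060.1 rose by log2 fold changes of 3.82 ± 0.79, 1.85 ± 0.33 and 2.04 ± 0.41 (SE). XR_002470672.1 (LOC110505001) fell from 4.64 ± 0.562 to 0.815 ± 0.332 FPKM, with a log2 fold change of -2.15 ± 0.39 SE (edgeR adjusted p = 0.028). Its nearest protein-coding gene is mmp17b, 1553 bases away, a matrix metalloproteinase. With a replicate block edgeR gave 46 calls in these 5 libraries. Control replicate 1 was alone in its block there, so that contrast rested on replicates 2 and 3 of each group. The 46 are therefore no stronger evidence than the 30. Without a block, edgeR gave 10 calls when control replicate 1 was left out too, with XR_002469880.1 and XR_002470209.1 alone of the 8. Leaving out control replicate 3 instead gave 7, with XR_002469880.1 alone. Without control replicate 2, XR_002470147.1, XR_002470060.1 and XR_002470284.1 were lost. The limits of XR_002469880.1 and XR_002469882.1 fell to 92.7-fold and 33.3-fold without control replicate 2 and to 91.1-fold and 32.7-fold without control replicate 3. Without heat replicate 2 edgeR gave 0 calls (66 at an unadjusted p under 0.05), and without heat replicate 3 also 0 (75 unadjusted). Each of these sets a single heat library against 3 controls, and the lone library is assumed to vary as the controls do. There the limit of XR_002469882.1 was 31.1-fold and the log2 fold change of XR_002470284.1 was 3.03 (both without heat replicate 2), and that of XR_002470119.1 was 2.58 in place of 3.35 (without heat replicate 3). Without control replicate 1 that of XR_002470284.1 was 4.44.

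Replicates 2 and 3 of each group shared 3413 transcripts, and 9 of 462 tested lncRNAs changed, 6 higher and 3 lower. Beyond those already named, XR_002473019.1 rose from 0.180 ± 0.0283 to 4.80 ± 0.141 FPKM (SD, n = 2 in each group; log2 fold change 5.07 ± 0.45 SE, edgeR adjusted p = 0.027). XR_002473514.1 fell from 63.3 ± 13.2 to 4.53 ± 1.12 FPKM (log2 fold change -3.43 ± 0.44 SE, edgeR adjusted p = 0.035). In edgeR there were 0 calls without control replicate 3 (80 at an unadjusted p under 0.05), 0 without heat replicate 2 (90 unadjusted) and 0 without heat replicate 3 (109 unadjusted). Without control replicate 2 XR_002473019.1 was still called and XR_002473514.1 was not. Each of these leaves 1 library on one side, assumed to vary as the other side does, so a count of 0 there does not show that nothing changed.

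The assembled lncRNAs had values in 3 libraries, control replicates 2 and 3 and heat replicate 2. Of 1511 transcripts tested there, 595 of them assembled, 21 differed at an adjusted p under 0.05 in edgeR, 16 higher and 5 lower in the heat library. Among the assembled ones, 9 were higher and 2 lower. The heat side is a single library with no replicate check, so SEs and p-values rest on the spread of the controls and describe that library, not heat. In simulation 19.8% of the calls of this fit were false. The simulated heat library varied as the controls do, so this share does not cover an atypical heat library. The count was 36 with size factors, and edgeR with library totals in place of TMM gave 0 calls (274 at an unadjusted p under 0.05). TCONS_00066339 stood at 1.13 and 0.42 FPKM in the controls and at 217.9 FPKM in the heat library (log2 fold change 8.50 ± 0.74 SE, edgeR adjusted p = 0.023). TCONS_00086882 stood at 0.09 FPKM in both controls and 3.31 FPKM in the heat library. It has 2 exons on the minus strand of NC_035093.1, from 61996307 to 62009031, and lies antisense to lbp/bpi-2, a gene of the lipopolysaccharide-binding and bactericidal protein family. Its reads cannot be told from those of that gene unless counting used strand. TCONS_00081166 stood at 0.29 and 0.14 FPKM in the controls and 3.71 FPKM in the heat library. Its 3 exons on the minus strand of NC_035092.1, from 41299444 to 41306063, share a splice junction with LOC110492088, the gene of XR_002468948.1. TCONS_00040144 (3.24 and 2.44 FPKM) and TCONS_00103408 (1.7 and 1.2 FPKM) had no read in the heat library, at least 60.1-fold and 62.7-fold lower. The known XR_002473865.1 (LOC110526055) stood at 11.95 and 9.71 FPKM in the controls and 139.7 FPKM in the heat library. Its gene span overlaps that of the protein-coding gene LOC110526054 in the reference table. Whether reads of LOC110526054 were counted for XR_002473865.1 is not known.

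The assembled transcripts with known exons were mostly made of few exons. Of 224, 160 had 2 exons and 64 had 3 or more, up to 9, and none had 1. Their exon length had a median of 1103 bases and ran from 219 to 6533. In the classes of the authors' table, 115 lay between known genes, 54 shared a splice junction with a known transcript, 41 overlapped a known exon in another way and 14 overlapped one on the opposite strand. They came from 216 loci on 29 sequences. For 86 of them the known gene of the authors' table was in the reference table, protein-coding for 58 and an lncRNA gene for 28. Parts of protein-coding transcripts may be among them, which was not tested. The build of these coordinates is not given in the sources used here.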

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

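The number of changed lncRNAs (18) stayed within 1.5 times its value in several alternatives. Requiring a log2 fold change of at least 1 could not alter it (18), since no call was below 1.77. It was 16 each with size factors, upper-quartile scaling and no filter, and 24 with a stricter filter. It was 23 and 22 with limma at pseudocounts of 0.1 and 0.01, and 18 with library totals in place of TMM. It moved to 35 with DESeq2 (23 higher, 12 lower), to 29 with limma on log2(FPKM + 1), with or without trend and robust fitting (17 higher, 12 lower), and to 42 with limma over transcripts held in at least 2 libraries of each group (22 higher, 20 lower). At an adjusted p under 0.01 it was 7, in the 5-library fit 30 and in the 4-library fit 9; the 3-library fit called 21. The limma fit on log2(FPKM + 1) with trend and robust fitting, the library totals and the fits on 5, 4 and 3 libraries were chosen after seeing the data. With one library left out the count ran from 7 to 22. A replicate block gave 9 calls, all among the 18. The sources used here do not say whether same-numbered libraries are paired. Their deviations from the group means correlated at -0.01, -0.02 and 0.11, and control replicate 1 correlated best with heat replicate 2, at 0.13. With so few libraries in a group, these values cannot settle whether there was pairing. In the 5-library fit control replicate 1 was alone in its block, so the block contrast rested on replicates 2 and 3 of each group. In the 5-library fit the block gave 46 calls and leaving out a library 0 to 30. In the 4-library fit leaving out a library gave 0 to 11. In the 3-library fit, library totals gave 0 calls (edgeR, 274 at an unadjusted p under 0.05) and size factors 36; the cause of these shifts was not tested. The 1 called lncRNA next to a gene of a fixed list became 0 within 10 kb and under the block, and ran from 0 to 1 with a library left out. The difference in detected lncRNAs ran from -29.0 to -7.00 and that in rho from 0.0617 to 0.0867 with a library left out, both keeping their sign. Taking transcripts beyond the end of an incomplete table as 0 was planned but not run, because those tables stop inside a line. In the main comparison 226 of 1498 lncRNAs had enough reads, and 35.0% of 4-fold changes were recovered in simulation.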

Other observations

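A few abundant transcripts lay outside the calls. XR_002469977.1, 1492 bases long, took 5.36%, 6.43% and 8.62% of all fragments in control replicates 1 to 3 and 8.18% and 13.4% in heat replicates 2 and 3. In the 5-library fit its log2 fold change was 1.01 ± 0.33 SE, which missed the threshold (edgeR adjusted p = 0.15). The assembled TCONS_00009843, with 3 exons on the minus strand of NC_035078.1 from 58578300 to 58579784, stood at 12253 FPKM in control replicate 2, 1344 FPKM in control replicate 3 and 1036 FPKM in heat replicate 2. TCONS_00066337 stood at 0.28 and 1.07 FPKM in the 2 controls and 227.9 FPKM in the heat library, close to the level of TCONS_00066339, but missed the threshold (edgeR adjusted p = 0.076). Of the known identifiers, 28 belong to genes that the newer gene table lists as protein-coding.

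The tests of consecutive identifiers against a shuffled list, with and without the leading 4 transcripts, were chosen only after the result was seen. For the 18 calls, 10 splits of 6 libraries are too few to reach a share under 0.05. The real split gave 18 calls, 1 split gave as many (the real one), and the highest of the others gave 0. Deeper sequencing of heat replicates 1 and 3 is argued against as the cause, since a median of 16 of the 18 calls (15 to 18 over 20 draws) remained when every library was thinned to 27.9 M fragments. A linear trend with transcript length gave a median of 0.0216 of a called change (quartiles 0.0121 and 0.0451). This argues against such a trend as the source of the called changes. It does not address whether longer transcripts were called more readily. The median length was 2008.5 bases for the called lncRNAs and 1540 for the tested ones. The labels give no sequencing batch. A response to heat and a difference between the tanks of the groups both stay open, as untested.

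Neighbouring identifiers often belong to transcripts of 1 gene or of adjacent genes. Over 60 pairs of tested lncRNAs with consecutive numbers, standardised log2 fold changes had a mean product of 1.09 (permutation p = 1e-05, the smallest that 100000 permutations can give), with 34 pairs of the same sign. This rested on the 4 transcripts from XR_002467886.1 to XR_002467889.1: without them the mean product over 57 pairs was 0.164 (permutation p = 0.0742). A candidate explanation is that these 4 are forms of 1 heat-responsive gene, but reads divided between similar transcripts could give the same picture. The 3 pairs with whole counts in every library (permutation p = 0.196) include none of these 4, so that test decides nothing about divided reads here, and both stay open.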
